A study of Mus musculus with 8 samples.

How the data were processed

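RNA was measured by sequencing in 8 libraries of CD4 T cells sorted from mouse spleen. Per the labels' protocols, wild-type (WT) and transgenic mice received tamoxifen on 5 consecutive days, cells were sorted directly into lysis buffer, and libraries were made with the SMART-Seq HT and Nextera XT kits. The labels give 3 groups. TIM3_GFPhi (n = 3, here GFPhi) holds TIM-3+, FLAG+, GFP+, FoxP3+ cells of mice that carry Foxp3-eGFP-Cre-ERT2 and FSF-TIM-3. TIM3_GFPlow (n = 3, here GFPlow) holds TIM-3+, FLAG+, GFP-, FoxP3- cells of the same genotype. WT_GFPpos (n = 2, here WT) holds TIM-3-, FLAG-, GFP+, FoxP3+ cells of mice with Foxp3-eGFP-Cre-ERT2 alone. Libraries are named by group and by the number in their titles.

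The authors deposited 1 table of counts, whole reads or read pairs per Ensembl gene with no normalization. HISAT2 2.1.0, SAMtools 1.9, HTSeq 0.11.2, edgeR and R 4.0 are named in the submitters' processing notes, with genome build GRCm38. The role of each tool, the annotation, the strand setting and the filters are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and genes with near-identical copies are uncertain. Of the 54837 identifiers in the table, 54808 were matched to GENCODE vM21 (GRCm38) for symbols and coordinates. No entry lacked a gene, and total counts ran from 44446215 to 55388756 per library. Counts of reads without molecular identifiers overstate the number of molecules, so limits taken from counts cover counting error only.

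From the counts, genes were kept by edgeR's filterByExpr with the 3 groups, which left 18851, and libraries were scaled by TMM. A single edgeR 4.0.16 model with 1 mean per group was fitted to all 8 libraries (estimateDisp, glmQLFit with robust estimation, 5 residual degrees of freedom). The 3 comparisons between groups were tested with the two-sided quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are given with their standard errors (SE), and abundances as TMM-scaled CPM, as mean ± SD, or as both values for WT. Foxp3 and Havcr2 were also compared between GFPhi and GFPlow by an exact two-sided permutation test of log2 CPM, whose smallest possible p is 0.1 for 3 against 3. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

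Gene groups were 18 lists of T cell biology (Treg identity, effector Treg, naive or central, co-inhibitory receptors, glycolysis, nuclear oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, cell cycle, immediate early, interferon-stimulated, T helper, follicular helper, homing, IL-2 and STAT5 response, apoptosis, cytotoxic granule, and genes common to T cells) and 10 lists of markers of other cells (B, plasma, myeloid, dendritic, neutrophil, NK, CD8, erythroid, platelet, stromal). Each list was tested against the other genes by limma camera on log2 CPM (prior count 2) with a correlation between genes of 0.01, and again with the correlation estimated per list. Adjustment was within each family of lists. Calls of single members are also given adjusted over the list alone. Some genes stand in several lists, such as Ctla4, Il2ra, Prf1 and Tbx21.

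The genes named follow a rule. Havcr2 and Foxp3 are always given. Among genes past the threshold with a mean log2 CPM above 3 and no overlap between the libraries of both groups, the 8 that rose and the 8 that fell most were named, without predicted genes, pseudogenes and receptor segments. Of each biology list, up to 4 members with the smallest adjusted p were named, and of each list of other cells the 2 most abundant members and those past the threshold. With fewer than 5 genes past the threshold, the 5 with the smallest p were named as values. Other genes are said to be chosen after their values were seen. The groups, tests, lists, naming rule and the alternatives not said to be added later were fixed before the data were examined.

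Alternatives were other scaling (median-of-ratios, upper quartile), no filter or a filter of 5 CPM in 2 libraries, DESeq2, limma voom with sample quality weights, no robust estimation, the replicate number as a block, only the libraries of both groups compared, a log2 change above 1, an estimated correlation for the lists, and each library left out in turn. Fits with DESeq2, with voom and with the block on the 7 libraries without WT library 1 were added after seeing that this library stood apart. With 1 WT library left out, the remaining one was assumed to vary like the libraries of the other groups. The model was tested on simulated data with 200 genes changed by known folds. Apart from these changes all simulated libraries shared 1 mean per gene. The shift of WT library 1 thus entered only through the spread of each gene, and recovery in the real data may differ. In the comparison of GFPhi with WT (18181 genes) it recovered 4.48% of genes changed 2-fold, 53.7% of those changed 4-fold and 89.4% of those changed 16-fold. The same shares were 7.46%, 44.8% and 87.9% for GFPlow against WT (18138 genes), and 5.97%, 70.1% and 90.9% for GFPhi against GFPlow (18105 genes). Without WT library 1 more 2-fold and 4-fold changes were recovered, with shares of 38.8%, 77.6% and 84.8% for GFPhi against WT, 40.3%, 59.7% and 87.9% for GFPlow against WT, and 55.2%, 79.1% and 97.0% for GFPhi against GFPlow. Unchanged genes called numbered 6, 8 and 4 in the 3 comparisons with all libraries, and 13, 11 and 16 without WT library 1.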

Results

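Gene expression was measured in 8 RNA sequencing libraries of CD4 T cells sorted from mouse spleen after tamoxifen. GFPhi (n = 3) and GFPlow (n = 3) are TIM-3+ FLAG+ cells of mice whose Foxp3 gene drives eGFP and a tamoxifen-activated Cre recombinase and that carry the FSF-TIM-3 transgene. They were sorted as GFP+ FoxP3+ (GFPhi) and as GFP- FoxP3- (GFPlow). WT (n = 2) are TIM-3- FLAG- GFP+ FoxP3+ cells of mice without the transgene. Total counts per library ran from 44446215 to 55388756, and 18851 genes were tested.

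Havcr2, the gene of the receptor TIM-3 (ENSMUSG00000020399, GRCm38 chromosome 11, 46454935 to 46481255), followed the sort labels in every library. Its abundance was 1464 ± 361 CPM (SD, n = 3) in GFPhi, 308.5 ± 210 CPM (SD, n = 3) in GFPlow, and 0.876 and 0.172 CPM in the 2 WT libraries, where 27 and 10 reads were counted. Foxp3, the lineage factor of regulatory T (Treg) cells (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), stood at 69.7 ± 10.5 CPM (SD, n = 3) in GFPhi, 3.08 ± 1.53 CPM (SD, n = 3) in GFPlow, and 41.7 and 63.2 CPM in WT. Both proteins were part of the gates, so these values check the labels and are no finding. In the exact two-sided permutation test of GFPhi against GFPlow, p was 0.1 for Havcr2 and 0.1 for Foxp3, the smallest that 3 against 3 libraries can give.

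WT library 1 stood apart from the other 7. It held counts in 18599 genes, against 21248 to 22185 elsewhere, and its counts were 6.54% mitochondrial (2.35% to 2.78% elsewhere) and 15.2% ribosomal protein (6.12% to 6.97% elsewhere). Its TMM factor was 0.694, against 1.041 to 1.07, and Pearson correlations of its log2 CPM across genes with other libraries were 0.853 to 0.885, while all other pairs reached 0.925 to 0.963. Xist, transcribed from the inactive X chromosome, was at 242 CPM in WT library 2, 237 in GFPhi library 3 and 184 in GFPlow library 3, and at 0.263 CPM or less in the other 5 libraries. The Y-linked gene Ddx3y ran from 170 to 229 CPM in those 5 libraries, was at 0 in GFPhi library 3 and GFPlow library 3, and was at 6.16 CPM in WT library 2. WT library 2 thus held both Xist and Y-linked counts (Eif2s3y at 8.9 CPM), and whether it holds RNA or reads of a second source is not known, which bears on each comparison with it alone.

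**Figure D1:**
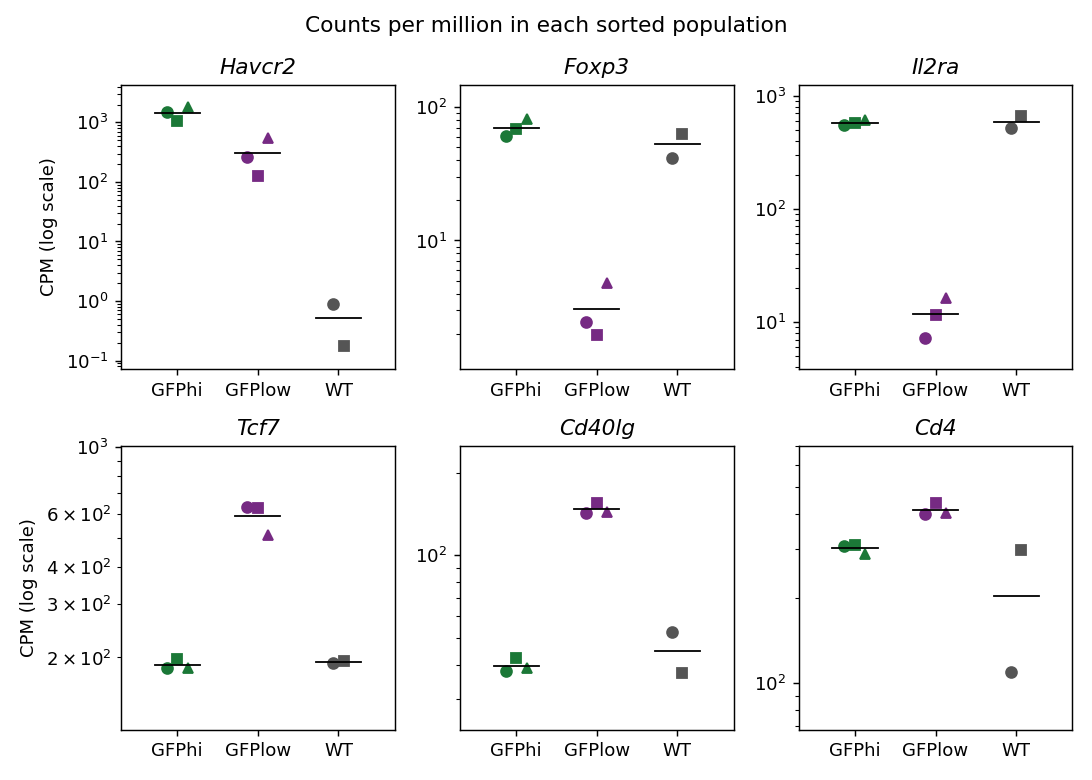
Abundance of 6 genes in each library on a log CPM axis, with 1 point per library and a bar at the mean of GFPhi (n = 3), GFPlow (n = 3) and WT (n = 2). Havcr2 separates both TIM-3+ sorts from WT, and Foxp3 and Il2ra separate GFPlow from both GFP+ sorts. Cd4 was chosen after its values were seen, as a marker of all sorted cells.

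**Figure D2:**
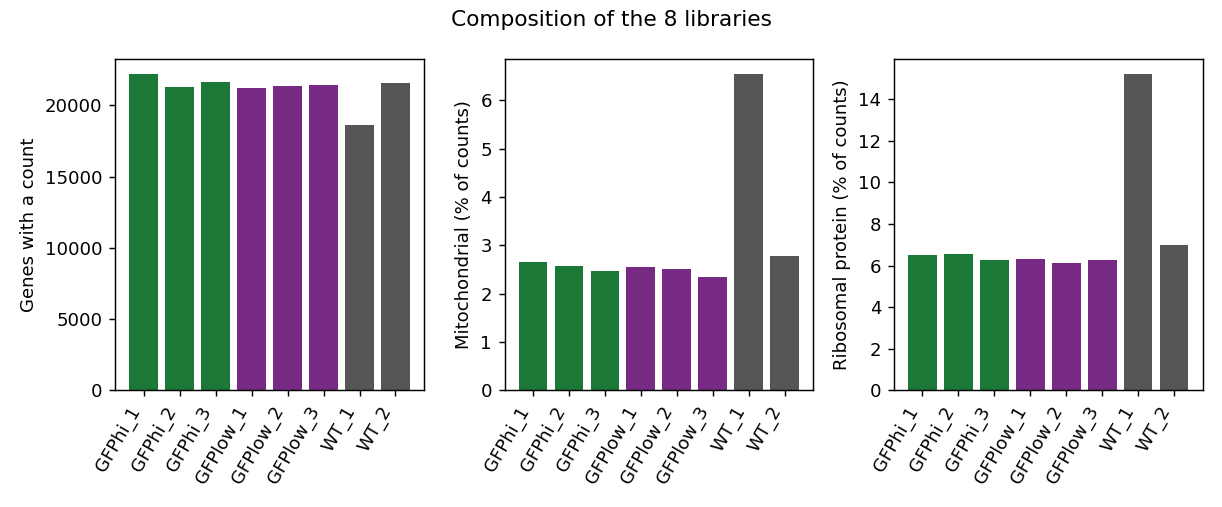
Number of genes with a count, and percent of counts from mitochondrial and ribosomal protein genes, with 1 bar per library. WT library 1 holds 18599 genes with a count and 15.2% ribosomal protein counts, outside the range of the other 7.

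The comparison of GFPhi with WT addresses the question in the series title, the effect of TIM-3 on Treg gene expression. Their gates differ too, TIM-3+ FLAG+ against TIM-3- FLAG-. An effect of the transgene and selection by these gates therefore cannot be told apart. Among the genes with the smallest p, Tbx21, which encodes the T helper 1 regulator T-bet, was at 6.04 ± 1.54 CPM (SD, n = 3) in GFPhi and at 1.59 and 1.78 CPM in WT. Myo1f, a class I myosin of blood cells, was at 29.7 ± 7.15 CPM in GFPhi and at 6.46 and 10.1 CPM in WT. Slco4a1, an organic anion transporter, had 0.974 ± 0.282 CPM in GFPhi and no count in either WT library. Against a floor of 3 counts over both it was at least 28.8-fold higher, a limit that covers counting error only. Among genes at 0.5 to 1 CPM elsewhere, 25% had no count in WT library 1 and 4.08% in WT library 2. The predicted gene Gm13340 was at 10.3 ± 2.89 CPM in GFPhi and at 44.2 and 90.6 CPM in WT. All 3 GFPhi libraries lay on the same side of both WT libraries for each of these genes. None passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. Havcr2, which the gate selects, did not pass either, so a gene without a call may still differ. Adjusted p was 0.121 for Havcr2 (log2 fold change 11.56 ± 1.13, SE) and 0.348 for Tbx21 (1.84 ± 0.32), Myo1f (1.84 ± 0.30), Slco4a1 and Gm13340 (-2.70 ± 0.44). Foxp3 differed by 0.41 ± 0.38 (adjusted p = 0.578).

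In that comparison edgeR called 0 genes, with 2588 at an unadjusted p under 0.05, of which 755 were higher and 1833 lower in GFPhi. DESeq2 called 320 genes, 6 higher and 314 lower, and limma voom called 0. Voom's sample quality weights were 0.133 and 0.181 for WT libraries 1 and 2, against 1.619 to 2.298 for the others. Its 0 is therefore no separate support for that of edgeR. Of the 314 genes lower under DESeq2, 61 carry symbols that begin like those of ribosomal protein genes, pseudogenes not excluded, and 7 are mitochondrial. Ribosomal protein and mitochondrial counts were raised in WT library 1. Without WT library 1 edgeR called 0 genes, DESeq2 72 (62 higher) and voom 1. Without WT library 2, so against WT library 1 alone, edgeR called 8234. Among all 18851 genes, the libraries of both groups did not overlap in 28.1%, against a chance share of 20% for 3 against 2.

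Nuclear oxidative phosphorylation genes were lower in GFPhi than in WT, with 39 of 46 below 0 and none past the threshold singly (30 lower when adjusted over the list alone). Cox6c, a subunit of cytochrome c oxidase, was at 334.7 ± 10.7 CPM in GFPhi and at 1986 and 358.6 CPM in WT libraries 1 and 2. Uqcrh, of respiratory complex III, was at 316.0 ± 20.9 against 1746 and 355.9 CPM. The list summed to 37280 CPM in WT library 1 and 13260 in WT library 2, and to 12740, 13600 and 12610 CPM in GFPhi libraries 1 to 3. By these sums GFPhi lay below WT library 1 and on both sides of WT library 2. Camera called the list lower (adjusted p = 2.1e-07), with an adjusted p = 0.776 with an estimated correlation and 0.202 without WT library 1.

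Homing receptor genes were higher in GFPhi (adjusted p = 0.0041 by camera, and adjusted p = 0.776 with an estimated correlation), 21 of 25 being above 0, with 0 called over all genes and 0 adjusted over the list alone. Cxcr6, a chemokine receptor of effector T cells, was at 68.6 ± 20.3 CPM in GFPhi and at 32.3 and 26 CPM in WT (1.23 ± 0.28, adjusted p = 0.348), and Cxcr3 at 102 ± 9.52 against 63.6 and 71.6 CPM. Without WT library 1 the homing list had an adjusted p of 0.0278, and an adjusted p = 0.288 with an estimated correlation. Glycolysis genes were higher as a list (adjusted p = 0.0103, and adjusted p = 0.776 with an estimated correlation), with 18 of 19 above 0 and 0 members called either way, including 0 adjusted over the list alone. Pkm, the last enzyme of glycolysis, was at 744 ± 69.5 CPM in GFPhi and at 110 and 540 CPM in WT. The glycolysis list had an adjusted p of 0.139 without WT library 1 and 0.0513 without GFPhi library 2, and it passed with any other library left out.

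The other 15 biology lists did not pass in GFPhi against WT, and none of their members was called over all genes. Of the effector Treg list 2 of 26 members were higher when adjusted over the list alone (camera adjusted p = 0.385). Il10, an anti-inflammatory cytokine gene of that list, was at 5.57 ± 1.97 CPM in GFPhi and at 0 and 0.362 CPM in WT (adjusted p = 0.348). Of the cytotoxic list 2 of 15 were higher when adjusted over the list alone (camera adjusted p = 0.594). Its member Eomes, a transcription factor of memory and cytotoxic T cells, was at 2.42 ± 1.37 CPM against 0.292 and 0.259 CPM, and Fasl, a death ligand, at 23.6 ± 2.8 against 6.29 and 13.3 CPM. Without WT library 1 both lists passed, with an adjusted p of 0.0278 each and an adjusted p = 0.288 with an estimated correlation. The IL-2 and STAT5 list (0.0587) and the T helper list (0.406) each had 1 member higher when adjusted over the list alone. The rest had 0, with adjusted p of 0.126 for cholesterol synthesis, 0.385 for cell cycle and immediate early genes, 0.521 for co-inhibitory receptors, 0.613 for apoptosis, 0.806 for naive or central genes, and 0.943 for Treg identity, fatty acid oxidation, interferon, follicular helper and common T cell genes. By voom without WT library 1 the Treg identity list passed as lower (0.0035, and adjusted p = 0.199 with an estimated correlation), and by edgeR without that library it had 0.139. With 1 library left out, the IL-2 and STAT5 list passed in 3 fits, without GFPhi library 1 (0.0488), GFPhi library 3 (0.0496) or GFPlow library 2 (0.0463), and with an estimated correlation the adjusted p was 0.838, 0.664 and 0.747. The cholesterol list passed without GFPhi library 1 (0.0401) or 3 (0.0496), and the cell cycle list without GFPhi library 3 (0.0159). With an estimated correlation these 3 had an adjusted p of 0.838, 0.664 and 0.696.

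Among markers of other cells in GFPhi and WT, the platelet list was lower in GFPhi (adjusted p = 0.00745, and adjusted p = 0.387 with an estimated correlation). None of its 6 tested genes was called over all genes and 3 were lower when adjusted over the list alone. Ppbp, a platelet chemokine, was at 0.05 ± 0.0866 CPM in GFPhi and at 26.7 and 1.26 CPM in WT libraries 1 and 2. Against WT library 2 alone the platelet list had an adjusted p of 6.34e-07, and an adjusted p = 0.123 with an estimated correlation. Against WT library 1 alone it had 0.87. The B (0.724), plasma (0.724), dendritic (0.724), myeloid (0.588), NK (0.872), CD8 (0.872), erythroid (0.872) and stromal (0.872) lists did not pass. They held 0 calls over all genes, and adjusted over the list alone 1 NK marker was higher. With the replicate number as a block the myeloid list passed as lower, with all libraries and with only those compared. The erythroid list passed with the block and only the libraries compared (camera adjusted p = 0.0372). The myeloid list passed as lower without GFPhi library 3 (0.00196) and without WT library 1 (0.0327), and with an estimated correlation the adjusted p was 0.928 and 0.659. Of the abundant markers, Cd79b was at 45.9 ± 3.67 CPM in GFPhi and 70.4 and 50.5 CPM in WT, and Cd74 at 110 ± 6.28 against 57.4 and 130 CPM. Of the neutrophil list only Mmp9 passed the filter on low counts, at 0.319 ± 0.213 CPM in GFPhi and 1.98 and 0.0172 CPM in WT, so the list was not tested.

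The comparison of GFPlow with WT sets cells that differ in both TIM-3 and GFP status side by side. Most Treg identity genes fell in GFPlow, 18 of 20. Il2ra, the high-affinity IL-2 receptor chain (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), was at 11.7 ± 4.49 CPM (SD, n = 3) in GFPlow and at 517 and 662 CPM in WT, a log2 fold change of -5.66 ± 0.36 (SE, adjusted p = 0.00122). Foxp3 fell by 4.09 ± 0.40 (adjusted p = 0.00371), and Lrrc32, which presents latent TGF-beta on Treg cells, fell by 6.25 ± 0.61 (adjusted p = 0.00371). Slc16a5, a monocarboxylate transporter, rose to 64.3 ± 12.1 CPM from 0.779 and 1.21 CPM in WT (adjusted p = 0.00122), and Sgk1, a kinase that responds to serum, glucocorticoids and salt, rose by 3.80 ± 0.27 (adjusted p = 0.00122). Havcr2 rose by 9.32 ± 1.04 (adjusted p = 0.00468), as the gate selects.

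In all, 623 genes passed edgeR's test in GFPlow against WT, 203 higher and 420 lower, and 602 of them by more than 2-fold. The libraries of both groups did not overlap for any of the 623, which a call itself makes likely. Among all 18851 genes they did not overlap in 40.3%, against a chance share of 20% for 3 against 2. Beyond the genes above, the 8 that rose most included Pde3b (5.41 ± 0.66), a cyclic nucleotide phosphodiesterase, Tdrp, Igfbp4 (3.17 ± 0.50), St3gal6, a sialyltransferase, and Rflnb, with adjusted p from 0.00494 to 0.0162. The 8 that fell most included Dnah7a (-6.10 ± 0.79), an axonemal dynein gene, the glutathione transferase gene Gsta4 (-5.22 ± 0.41), Pdzk1ip1, Rgs1, a regulator of G protein signalling, Penk, which encodes proenkephalin (-4.36 ± 0.47), and Bicd1, with adjusted p from 0.00146 to 0.00737.

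The Treg identity list includes Foxp3, on which the sorts were gated, so its direction is no finding independent of the gate. Of the 20 Treg identity genes, 18 fell in GFPlow against WT and 20 fell when adjusted over the list alone (camera adjusted p = 1.19e-20, and adjusted p = 0.0259 with an estimated correlation). Besides Il2ra they included the costimulatory receptor genes Tnfrsf4 (-3.53 ± 0.27) and Tnfrsf9 (-2.49 ± 0.24) and the inhibitory receptor gene Ctla4 (-2.60 ± 0.20). Of 26 effector Treg genes, 6 fell and 2 rose (16 and 3 adjusted over the list alone), and the list was lower (adjusted p = 0.0021, and adjusted p = 0.0542 with an estimated correlation). Il1r2, a decoy receptor for IL-1 (-3.94 ± 0.57), Ebi3, a subunit of IL-35 (-2.91 ± 0.42), and the chemokine receptor gene Ccr8 (-2.62 ± 0.38) fell, and Tbx21 rose by 3.33 ± 0.34 to 17 ± 1.46 CPM (adjusted p = 0.00379).

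Naive or central T cell genes were higher in GFPlow than in WT (adjusted p = 0.000182, and adjusted p = 0.042 with an estimated correlation), with 5 of 16 risen and 1 fallen (10 and 2 adjusted over the list alone). The transcription factor genes Tcf7 (1.61 ± 0.20), Lef1 (1.80 ± 0.26) and Satb1, a chromatin organiser, rose, as did the IL-7 receptor gene Il7r (1.47 ± 0.23). Tcf7 was at 590 ± 68.3 CPM in GFPlow and at 192 and 194 CPM in WT. Bcl2, a survival gene of this list, fell (-1.04 ± 0.21, adjusted p = 0.0387), and was called in 2 of the 8 fits with 1 library left out, those without a WT library.

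Cytotoxic granule genes were higher in GFPlow (adjusted p = 0.000114, and adjusted p = 0.042 with an estimated correlation), 5 of 15 having risen and 1 fallen (6 and 1 adjusted over the list alone). Camera weighs genes alike, whatever their abundance. The list summed to 725.3, 804 and 863 CPM in GFPlow and to 1422 and 666.7 CPM in WT libraries 1 and 2, so its total was not above both WT libraries. Gzmk, a granzyme, was at 9.49 ± 4.94 CPM in GFPlow with no count in either WT library, at least 281-fold higher against a floor of 3 counts over both. Klrk1, the receptor NKG2D, was at 22.1 ± 17.7 CPM, at least 654-fold higher by the same floor. Eomes rose by 4.93 ± 0.66 and the perforin gene Prf1 by 2.72 ± 0.55, while Cst7, an inhibitor of cathepsins, fell by 2.88 ± 0.27. The NK marker list, which shares Eomes, summed to 24.43, 19.99 and 96.57 CPM in the 3 GFPlow libraries and to 16.81 and 8.741 CPM in WT (adjusted p = 0.684, 1 of 6 risen, 2 adjusted over the list alone). Against WT library 1 alone the cytotoxic list had an adjusted p of 0.115.

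Homing genes were higher in GFPlow than in WT (adjusted p = 0.00606, and adjusted p = 0.399 with an estimated correlation), with 3 of 25 risen and 2 fallen (7 and 2 adjusted over the list alone). Cxcr6 rose by 2.92 ± 0.31 to 221 ± 34.3 CPM, Cxcr3 by 1.28 ± 0.20, and S1pr4, a sphingosine 1-phosphate receptor, by 1.27 ± 0.24. Oxidative phosphorylation genes were lower (adjusted p = 1.67e-05, and adjusted p = 0.483 with an estimated correlation), with 0 of 46 called and 33 lower when adjusted over the list alone. Uqcrb, of respiratory complex III, was at 196 ± 16.1 CPM in GFPlow and at 1339 and 256.9 CPM in WT libraries 1 and 2, and without WT library 1 the list had an adjusted p of 0.0194, and an adjusted p = 0.705 with an estimated correlation. Cholesterol synthesis genes were higher (adjusted p = 0.0106, and adjusted p = 0.483 with an estimated correlation), with 19 of 20 above 0 and 0 called, also adjusted over the list alone. Insig1, a sterol sensor, was at 23.1 ± 3.6 CPM in GFPlow and at 5.87 and 13.8 CPM in WT.

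The other lists did not pass in GFPlow against WT, though single members did. T helper genes (adjusted p = 0.0872) held 3 that rose and 1 that fell of 17 (4 and 2 adjusted over the list alone), with Cd40lg, the helper ligand for B cells, up by 1.72 ± 0.21 and Lta, lymphotoxin alpha, down (-2.31 ± 0.17). Of 15 co-inhibitory genes (0.0884), 3 fell (4 adjusted over the list alone), the ectonucleotidase gene Entpd1 by -2.57 ± 0.28 among them. IL-2 and STAT5 genes (0.304) held 1 that rose and 4 that fell of 16 (4 and 6 adjusted over the list alone), such as the signalling inhibitors Socs2 (-3.99 ± 0.52) and Cish (-2.24 ± 0.39). Apoptosis genes (0.189) held 1 that rose and 3 that fell of 23 (1 and 7 adjusted over the list alone), with Fasl up by 2.20 ± 0.33 and Tnfsf10, the death ligand TRAIL, down (-1.29 ± 0.23). In glycolysis (0.0622) Pdk1, a kinase that restrains pyruvate oxidation, rose by 1.57 ± 0.19 and the hexokinase gene Hk2 fell (-3.67 ± 0.60), 1 each of 19 (2 and 1 adjusted over the list alone). Without WT library 1 the co-inhibitory (0.0109), IL-2 and STAT5 (0.0335) and apoptosis (0.0354) lists passed as lower, and without WT library 2 the glycolysis list passed as higher (0.00694). With an estimated correlation these 4 had an adjusted p of 0.122, 0.251, 0.181 and 0.222.

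Among the remaining lists of GFPlow against WT, immediate early genes (adjusted p = 0.561) held 1 that rose, Zfp36, and 1 that fell, Nr4a3, of 22 (2 and 4 adjusted over the list alone). In fatty acid oxidation (0.777) Decr1 fell, 1 of 18 (2 adjusted over the list alone), in the follicular helper list (0.89) Cd200 fell, 1 of 13 (1 rose and 2 fell adjusted over the list alone), and among common T cell genes (0.302) 1 of 14 rose (1 rose and 1 fell adjusted over the list alone). Cell cycle (0.0884, 30 genes) and interferon genes (0.304, 24 genes) held 0 calls, also adjusted over the list alone. The cell cycle list passed as lower without GFPlow library 3 (0.00156), and the common T cell list as higher without WT library 1 (0.0354), and with an estimated correlation the adjusted p was 0.503 and 0.185. Of markers of other cells no list passed, with adjusted p of 0.684 for B, NK, CD8, erythroid and platelet markers and 0.883 for plasma, myeloid, dendritic and stromal markers. Cd79b, a subunit of the B cell receptor, fell (-3.35 ± 0.53, 5.95 ± 4.55 CPM in GFPlow), as did Cd74, the invariant chain (-2.51 ± 0.32), and Col1a2, a collagen gene with no count in any GFPlow library against 4.83 and 0.448 CPM in WT. The integrin gene Itgb3 rose by 1.85 ± 0.26 to 79.9 ± 9.52 CPM, and Car2, a carbonic anhydrase of the erythroid list, by 2.60 ± 0.53. Over the list alone, 1 gene of each of the B, myeloid and erythroid lists was called, 1 platelet and 1 stromal marker rose and 1 of each fell, and 0 plasma, dendritic and CD8 markers were called. The neutrophil list, with Mmp9 alone past the filter, was not tested. Mmp9 was at 2.80, 2.93 and 10.7 CPM in GFPlow and at 1.98 and 0.0172 CPM in WT.

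The count of 623 rested on the libraries in the fit. It was 312, 302 and 329 without GFPhi libraries 1, 2 and 3, and 213, 227 and 227 without GFPlow libraries 1, 2 and 3. It was 1209 without WT library 1 (554 of them among the 623) and 9002 without WT library 2. DESeq2 called 3243 genes, including all 623, and limma voom with sample quality weights 74. Of the 58 genes that the naming rule gives and that passed, 34 passed in all 8 fits with 1 library left out, Il2ra, Lrrc32, Tcf7, Lef1, Cxcr6, Eomes and Tbx21 among them. The other 24 lost the call in at least 1. They include, each with its highest adjusted p over these fits, Bcl2 0.178, Bcl2a1b 0.128, Car2 0.128, Ccr8 0.0618, Cd200 0.0802, Cd79b 0.0722, Cish 0.109, Col1a2 0.115, Cxcr3 0.0753, Decr1 0.121, Ebi3 0.0619, Fasl 0.0578, Gzmk 0.0562, Hk2 0.0845, Igfbp4 0.0621, Il18r1 0.149, Il1r2 0.0625, Il7r 0.0716, Nr4a3 0.161, Prf1 0.119, S1pr4 0.114, Tnfsf10 0.116 and Zfp36 0.123.

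GFPhi and GFPlow carry the same genotype and differ in the GFP gate. In GFPhi the Treg identity genes were higher. Il2ra was at 577.5 ± 30.9 CPM (SD, n = 3) in GFPhi and 11.7 ± 4.49 CPM (SD, n = 3) in GFPlow, a log2 fold change of 5.63 ± 0.35 (SE, adjusted p = 0.00103). Foxp3 rose by 4.50 ± 0.39 (adjusted p = 0.00218), and Lrrc32 by 6.54 ± 0.61 (adjusted p = 0.0026). Slc16a5 fell in GFPhi (-3.96 ± 0.32, adjusted p = 0.00188), as did Pde3b (-4.32 ± 0.52, adjusted p = 0.00641) and Sgk1 (-3.04 ± 0.22, adjusted p = 0.00138). Havcr2 was 2.25 ± 0.61 higher on the log2 scale in GFPhi (adjusted p = 0.134), in all 3 libraries against each GFPlow library.

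In GFPhi against GFPlow, 426 genes passed, 308 higher and 118 lower in GFPhi, and 402 of them by more than 2-fold. None of the 426 had overlapping libraries, and 30% of all genes were separated in this way, where chance gives 10%. In 421 of the 426 genes (98.8%) the fitted mean of GFPhi lay nearer to WT than that of GFPlow did. The comparisons of GFPlow with WT and of GFPhi with GFPlow shared 346 calls, of which 255 were lowest and 91 highest in GFPlow. Both use the same GFPlow libraries, so this is not an overlap of independent comparisons. The largest rises also took in Dnah7a, Penk (4.89 ± 0.47), Gsta4, Pdzk1ip1 and Bicd1, with adjusted p from 0.00201 to 0.0117. The largest falls took in Dapl1 (-3.85 ± 0.56), a naive T cell gene, the chemokine gene Ccl5, Tdrp, Amigo2, a cell adhesion gene, and Rapgef4, an exchange factor that binds cyclic AMP, with adjusted p from 0.00555 to 0.0458.

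**Figure D3:**
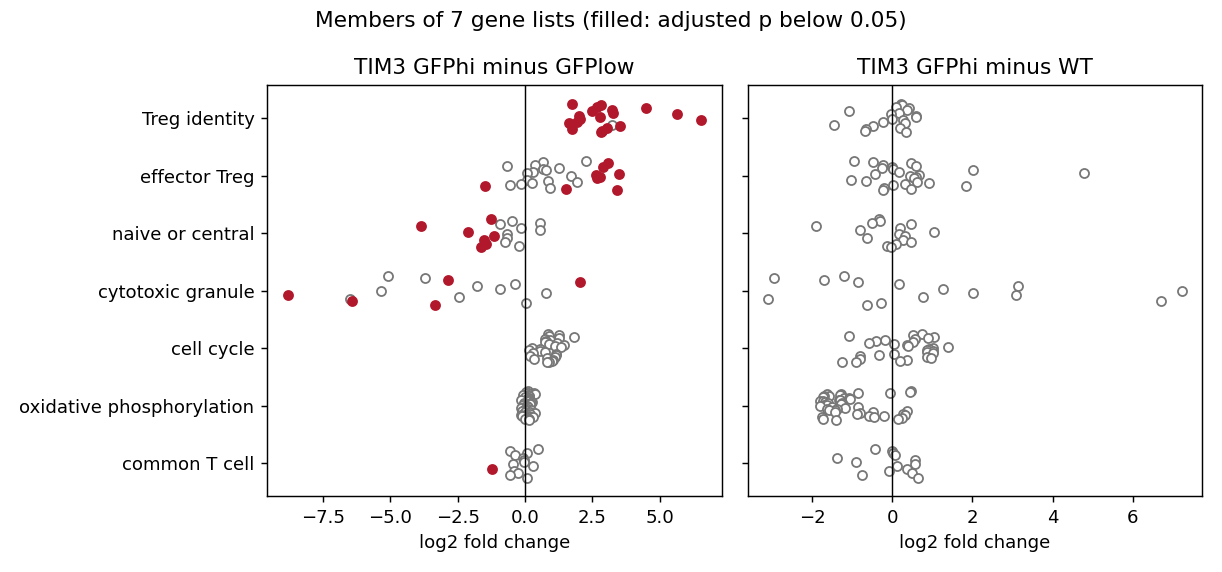
Log2 fold change of each tested member of 7 gene lists, in GFPhi minus GFPlow and in GFPhi minus WT, with filled points for adjusted p below the threshold of 0.05. All 20 Treg identity genes lie above 0 against GFPlow, and no gene of these lists is past the threshold against WT.

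Of the 20 Treg identity genes, 19 rose in GFPhi against GFPlow (20 adjusted over the list alone, camera adjusted p = 1.79e-34, and adjusted p = 0.00776 with an estimated correlation). They include Foxp3, on which the sorts were gated, so the direction of this list is no finding independent of the gate. Ctla4 rose by 2.83 ± 0.20, Tnfrsf9 by 2.82 ± 0.23 and Tnfrsf4 by 2.86 ± 0.25. Of the 26 effector Treg genes, 8 rose and 1 fell (13 and 2 adjusted over the list alone, adjusted p = 1.12e-07, and adjusted p = 0.00896 with an estimated correlation). Ccr8 rose by 3.09 ± 0.36, Ebi3 by 2.91 ± 0.40, the integrin gene Itgae by 2.77 ± 0.41 and Il1r2 by 3.50 ± 0.54. Co-inhibitory genes were higher (adjusted p = 0.00144, and adjusted p = 0.194 with an estimated correlation), and 3 of 15 rose (4 adjusted over the list alone), namely Ctla4, Entpd1 (2.68 ± 0.26) and Cd200 (1.34 ± 0.18). Of the 16 IL-2 and STAT5 genes, 4 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 6.06e-05, and adjusted p = 0.177 with an estimated correlation), among them Cish (2.83 ± 0.37), Socs2 (3.50 ± 0.49) and the fallen Prf1.

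Naive or central genes were lower in GFPhi than in GFPlow (adjusted p = 1.07e-09, and adjusted p = 0.00875 with an estimated correlation), 7 of 16 having fallen (11 lower and 1 higher adjusted over the list alone). Satb1 was at 143 ± 6.31 CPM in GFPhi and 395 ± 13.4 CPM in GFPlow (-1.47 ± 0.15), Tcf7 fell by 1.64 ± 0.17 and Lef1 by 1.54 ± 0.22. Cytotoxic granule genes were lower too (adjusted p = 1.84e-07, and adjusted p = 0.0104 with an estimated correlation), with 4 of 15 fallen and 1 risen (9 and 1 adjusted over the list alone). Their sums overlapped between the sorts, at 825.1, 752.9 and 605.6 CPM in GFPhi and 725.3, 804 and 863 CPM in GFPlow. Prf1 was at 2.46 ± 0.751 CPM in GFPhi and 24.8 ± 2.42 CPM in GFPlow, Gzmk at 0.0187 ± 0.0325 against 9.49 ± 4.94 CPM, and Klrk1 at 0.256 ± 0.00951 against 22.1 ± 17.7 CPM, while Cst7 rose by 2.02 ± 0.25. NK markers were lower in GFPhi as well (adjusted p = 0.0205, and adjusted p = 0.51 with an estimated correlation), and Klrb1c, the NK receptor NK1.1, fell (-3.38 ± 0.64, adjusted p = 0.0353), 1 of 6 (2 adjusted over the list alone). The NK list had an adjusted p of 0.331 without GFPlow library 3, 0.0558 without GFPhi library 1, and 0.0923 and 0.079 without WT libraries 1 and 2.

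Cell cycle genes were higher in GFPhi than in GFPlow as a list (adjusted p = 1.06e-05, and adjusted p = 0.397 with an estimated correlation), all 30 lying above 0 and 0 being called, also adjusted over the list alone. Mki67, a marker of cycling cells, was at 62.8 ± 32.2 CPM in GFPhi and 28.4 ± 13.7 CPM in GFPlow. The sums of the list overlapped between the sorts, at 2807, 1983 and 1497 CPM in the GFPhi libraries 1 to 3 and 1127, 1212 and 1818 CPM in the GFPlow libraries 1 to 3. Immediate early genes were higher as a list (adjusted p = 0.0114, and adjusted p = 0.357 with an estimated correlation) with 0 of 22 called, also adjusted over the list alone, and that list did not pass without GFPhi library 1 (0.237) or GFPlow library 3 (0.0585). Nr4a1, induced by T cell receptor signals, was at 35.2 ± 12.1 against 16.1 ± 2.01 CPM. Apoptosis genes were higher (adjusted p = 0.00283, and adjusted p = 0.0582 with an estimated correlation), with 2 of 23 risen (3 adjusted over the list alone), among them Tnfsf10 by 1.30 ± 0.22.

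The other lists did not pass in GFPhi against GFPlow. Of 17 T helper genes (adjusted p = 0.128), Lta rose by 2.16 ± 0.16, and Cd40lg (-1.90 ± 0.18) and Tbx21 (-1.49 ± 0.27) fell (3 higher and 5 lower adjusted over the list alone). Of 25 homing genes (0.149), Ccr8 and Itgae rose and Cxcr6 fell (-1.69 ± 0.25), with 3 higher and 6 lower adjusted over the list alone. Pdk1 fell (-1.45 ± 0.17) and Hk2 rose (3.15 ± 0.57) among glycolysis genes (0.749, 1 and 1 adjusted over the list alone). Cd200 was the 1 call of the follicular helper list (0.749, 1 adjusted over the list alone) and the common T cell list held 1 that fell (0.0808, 1 adjusted over the list alone). Oxidative phosphorylation (0.749), fatty acid oxidation (0.42), cholesterol (0.128) and interferon genes (0.149) held 0 calls, also adjusted over the list alone. With 1 library left out, the interferon list passed as lower without GFPhi library 3 (0.00152) or GFPlow library 1 (0.0373) or 2 (0.0281), and the cholesterol list without GFPhi library 2 (0.0063). With an estimated correlation these 4 had an adjusted p of 0.382, 0.662, 0.671 and 0.283. The common T cell list passed as lower without WT library 1 (0.00919) or 2 (0.0104), and oxidative phosphorylation as higher without WT library 2 (0.0401), against an adjusted p of 0.108, 0.127 and 0.728 with an estimated correlation. Oas2, an interferon-induced gene, was at 10.1 ± 8.2 CPM in GFPhi and 39.2 ± 12.4 CPM in GFPlow (adjusted p = 0.155).

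Of markers of other cells in GFPhi and GFPlow, platelet markers were lower in GFPhi (adjusted p = 0.0205, and adjusted p = 0.51 with an estimated correlation) with 1 call, Itgb3 (-1.45 ± 0.22, 29.2 ± 4.88 CPM in GFPhi), also adjusted over the list alone. That list did not pass without GFPhi library 1 (0.0558), GFPlow library 2 (0.167), or WT library 1 (0.141) or 2 (0.0803). Cd79b (2.95 ± 0.50) and Cd74 (2.74 ± 0.30, 110 ± 6.28 against 16.4 ± 2.04 CPM) rose, the 1 call each of the B (0.522) and myeloid (0.0705) lists, adjusted over the list alone too. Plasma (0.278), dendritic (0.199), CD8 (0.278), erythroid (0.315) and stromal (0.522) lists held 0 calls over all genes, and 1 plasma and 1 stromal gene were higher when adjusted over the list alone. Left-out libraries moved 4 of these lists past the threshold. The myeloid list was lower without GFPhi library 3 (8.94e-05) or GFPlow library 2 (0.00242), and the erythroid list without GFPlow library 1 (0.0314), against an adjusted p of 0.386, 0.363 and 0.596 with an estimated correlation. The dendritic list was higher without GFPlow library 2 (0.0465) or 3 (0.00592), and the B list without GFPlow library 2 (0.0345), against an adjusted p of 0.334, 0.267 and 0.334 with an estimated correlation. Lyz2, an abundant lysozyme gene of myeloid cells, was at 197 CPM in GFPlow library 3 and at 15 and 0.224 CPM in GFPlow libraries 1 and 2. In GFPhi its mean was 2.12 ± 2.48 CPM. Mmp9, the only neutrophil marker past the filter, was at 0.206, 0.565 and 0.185 CPM in GFPhi and at 2.80, 2.93 and 10.7 CPM in GFPlow, and the neutrophil list was not tested.

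The count of 426 also moved with the libraries in the fit. It was 105, 128 and 177 without GFPhi libraries 1, 2 and 3, and 142, 148 and 158 without GFPlow libraries 1, 2 and 3. It was 1984 without WT library 1 and 1978 without WT library 2, and each of these included all 426. DESeq2 called 1375 genes, including all 426, and voom 2277, including 422. Of the 47 genes that the naming rule gives and that passed, 21 passed in all 8 fits with 1 library left out, Il2ra, Foxp3, Lrrc32, Ctla4, Ccr8, Satb1, Tcf7 and Cd40lg among them. The other 26 lost it in at least 1, and include, each with its highest adjusted p, Amigo2 0.0743, Ccl5 0.231, Cd200 0.0664, Cd79b 0.103, Cish 0.0587, Cst7 0.0507, Cxcr6 0.0963, Dapl1 0.092, Dnah7a 0.0516, Ebi3 0.0617, Gzmk 0.0541, Hk2 0.138, Il1r2 0.091, Itgae 0.0829, Itgb3 0.0994, Klrb1c 0.174, Klrk1 0.107, Lef1 0.0887, Pdzk1ip1 0.0713, Prf1 0.0792, Socs2 0.0584, Tbx21 0.147, Tdrp 0.0605 and Tnfsf10 0.117.

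Fold changes of GFPhi and GFPlow against the same 2 WT libraries had a Pearson correlation of 0.668 across genes, which are not independent replicates, and the same sign in 81.4% of genes. In 20 draws all 8 libraries, WT included, were simulated from 1 mean per gene, which gave 0.636 (0.607 to 0.655) and 70.6%. The real WT libraries were not used in these draws, so the difference between them entered only as spread. The covariance of edgeR fold changes was 1.868, against 0.665 (0.614 to 0.702) when simulated. The difference between both WT libraries gave 0.894, but on log2 CPM with a prior count of 2, which is not the same scale. The WT libraries were not split, since each part would hold 1. How much of any excess comes from the shared WT libraries therefore cannot be told. No overlap of calls can be weighed for edgeR, which called 0 genes in GFPhi against WT. By DESeq2, 3 genes were shared among those higher and 280 among those lower, and without WT library 1 these counts were 56 and 6. Independent lists give 0.368 and 34.8, and 3.76 and 0.586 without WT library 1, but these values leave out the shared WT libraries, and no unchanged groups were simulated for DESeq2.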

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

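Of the settings here, the fits by DESeq2, voom and the block on the 7 libraries without WT library 1 were chosen after that library was seen to stand apart. All others were planned. Each library held at least 44446215 counts. In the simulated data, recovery of 2-fold changes moved with WT library 1, from 4.48% with it to 38.8% without it in GFPhi against WT, and from 5.97% to 55.2% in GFPhi against GFPlow. Limits from depth or from the number of libraries were not tested. Of 292 values of single genes, 286 are not of Havcr2 or Foxp3. In each setting most of these kept their direction and their side of the threshold, all 286 with median-of-ratios scaling, 279 with upper quartile scaling, 284 without robust estimation, and at the lowest 159 against WT library 1 alone. Signs turned in 104 cases, spread over 27 of the 292 values, and in 2 cases the turned value was past the threshold.

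The genes called in GFPhi against WT, GFPlow against WT and GFPhi against GFPlow were 0, 623 and 426. With both other scalings, the stricter filter and no robust estimation all 3 stayed within 1.5 times of that. Without a filter 1 gene was called in GFPhi against WT. DESeq2 called 320, 3243 and 1375. Voom with sample quality weights, which gave both WT libraries little weight, called 0, 74 and 2277. A fit to only the libraries compared called 0, 33 and 2105. With 1 library left out the counts ran from 0 to 8234, from 213 to 9002 and from 105 to 1984, with both highest values against WT coming from the fit on WT library 1 alone. Without WT library 1, DESeq2 called 72, 2449 and 3246, and voom 1 (Gm13340), 1509 and 2172. In GFPhi against GFPlow the count was lower with any transgenic library left out. It was higher in the fit without WT libraries (2105) and by voom with little weight on them (2277). Both WT libraries differed with an SD over genes of 1.145 in log2 CPM, against at most 0.350 for other pairs of 1 group. That spread enters the main fit, in which all groups share 1 estimate. The use of fewer libraries therefore does not account for these rises, and their cause was not tested further.

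Genes called in the same direction in both sorts against WT numbered 0. They were 1 without a filter, 283 by DESeq2, 62 by DESeq2 without WT library 1, 1 by voom without it, and 0 to 7317 with 1 library left out. Biology lists past the threshold were 3, 7 and 9. In GFPhi against WT they were 5 without a filter, 5 by voom with weights, 6 by voom without WT library 1 and 2 to 6 with 1 library left out. In GFPlow against WT they were 11 by voom with weights, 13 by voom without WT library 1 and 7 to 11 with 1 library left out, and in GFPhi against GFPlow 8 to 11 with 1 library left out, 11 by voom with weights and 12 by voom without WT library 1. The 6 by voom without WT library 1 in GFPhi against WT were Treg identity genes, lower (0.0035), and effector Treg, glycolysis, cholesterol, cell cycle and homing genes, higher (0.012 each). With an estimated correlation Treg identity, effector Treg and homing genes had an adjusted p of 0.199 there, and none of the 6 passed. With all libraries and an estimated correlation 0, 3 and 4 lists passed in the 3 comparisons. The cause was not tested.

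Havcr2 in GFPhi against WT (11.56, adjusted p = 0.121) passed without a filter (11.61, 0.0253), by DESeq2 (11.46, 4.34e-56) and by DESeq2 without WT library 1 (13.05, 1.31e-40). It ran from 10.73 to 13.03 with 1 library left out and passed there against WT library 1 alone (0.0017). In GFPlow against WT (9.32) it did not pass by voom with weights (9.76, 1), with only the libraries compared (9.28, 0.0689) or by voom without WT library 1 (10.45, 0.707), and ran from 8.48 to 10.79. In GFPhi against GFPlow (2.25, adjusted p = 0.134) it passed by DESeq2 (2.23, 0.00451), voom with weights (2.46, 0.0136), with only the libraries compared (2.24, 0.0472), without WT library 1 (2.24, 0.0485) and by DESeq2 without it (2.24, 0.00104), and ran from 1.88 to 2.92. Foxp3 ran from 0.14 to 0.77, from -4.57 to -3.73 and from 4.26 to 4.98 in the same 3 comparisons. In GFPlow against WT it did not pass with only the libraries compared (-4.09, 0.0641). The cause was not tested.

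The replicate number as a block moved the counts to 0, 158 and 182. With only the libraries compared the block gave 22, 217 and 1752, and without WT library 1 it gave 4 (Havcr2, Kdm5d, Ddx3y and Xist), 720 and 1744. The block also ties WT libraries to transgenic libraries of the same number, though WT mice are other animals of another genotype. WT library 2 held 242 CPM of Xist and 6.16 CPM of Ddx3y, against 0.263 and 201 CPM in GFPhi library 2. Calls of Kdm5d, Ddx3y and Xist follow this mismatch, and the block is no pairing by design in comparisons with WT. Correlations of the deviations of GFPhi and GFPlow libraries of the same number were 0.0671, 0.0662 and 0.149. The titles carry the same numbers in both transgenic sorts, but do not say whether these mark the same mice. Every transgenic sample correlated best with its own number. Xist was at 237 and 184 CPM in the number 3 libraries of both sorts, and Fos at 153.1 and 195.2 CPM in the number 1 libraries. If these are pairs, the main test of GFPhi against GFPlow left the pairing out. Havcr2 in GFPhi against WT passed under the block with only the libraries compared (11.61, 1.5e-13) and without WT library 1 (12.31, 0.0109), and against GFPlow with 2.46 (0.00376) and 2.45 (0.00305). Calls in both sorts against WT numbered 4 under the block without WT library 1, and 1 biology list passed there in GFPhi against WT. That list was cholesterol (adjusted p = 0.000673, and adjusted p = 0.652 with an estimated correlation), with 0.114 on the same 7 libraries without the block. Effector Treg, homing and cytotoxic genes had 0.0278 each without the block there (adjusted p = 0.288 each with an estimated correlation) and 0.0542 each with it. Glycolysis (0.139 without and 0.182 with the block) and oxidative phosphorylation (0.202 and 0.466) passed in neither. In GFPlow against WT oxidative phosphorylation had 0.0194 without the block (adjusted p = 0.705 with an estimated correlation) and 0.0921 with it, and further lists of that comparison also passed only without the block. The common T cell list in GFPhi against GFPlow passed in both at a correlation of 0.01. With an estimated correlation it did not pass without the block. With the block and only the libraries compared, homing had 0.0822 in GFPhi against WT and 0.0692 in GFPlow against WT, and cholesterol 0.0856 in GFPlow against WT. Lists that passed there, though not with all libraries and no block, were cell cycle (0.0493) and IL-2 and STAT5 (0.0493) in GFPhi against WT, cell cycle in GFPlow against WT (0.000214) and common T cell genes in GFPhi against GFPlow (0.0318). With all libraries, no block and an estimated correlation, camera gave them an adjusted p of 0.964, 0.776, 0.782 and 0.194. The block alone brought 1 list past the threshold, glycolysis in GFPlow against WT (0.0494), and changed no other call of a biology list. Without the block, camera with an estimated correlation gave that list an adjusted p of 0.534.

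Other values turned in sign under the block. Under the block alone they were -0.71 for Fcer1g in GFPhi against WT; in GFPlow against WT -2.14 for Lyz2, -1.85 for Fcer1g, 0.0381 for Cd8b1 and -4.73 for Hba-a1; in GFPhi against GFPlow 0.0485 for Hba-a1. With only the libraries compared the block gave 0.12 for Cd22, 0.0847 for Zbtb46, 0.41 for Mmp9 and -0.50 for Fcer1g in GFPhi against WT, and -2.62 for Lyz2, -2.41 for Fcer1g and -4.59 for Hba-a1 in GFPlow against WT. With the block and without WT library 1, GFPhi against WT gave -0.0917 for Foxp3, 0.80 for Cd244a, 0.0571 for Etfa, 0.00189 for Cd22, -0.13 for Xbp1, -0.17 for Irf4, -0.30 for Cd74, 0.19 for Bst2, 0.44 for Zbtb46, 4.20 for Mmp9, -0.81 for Fcer1g, 0.32 for Cd8b1, -0.59 for Cd8a and 0.83 for Col1a2. GFPlow against WT gave -5.52 for Lyz2, 0.0858 for Bst2, 0.14 for Zbtb46, -1.89 for Fcer1g, 0.58 for Cd8b1, -2.63 for Hba-a1 and 0.44 for Ppbp there. None of these passed, and the cause was not tested.

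DESeq2 without WT library 1 turned the sign in GFPhi against WT of Cd244a (1.38), Etfa (0.00348), Xbp1 (-0.11), Cd74 (-0.24), Bst2 (0.22), Zbtb46 (0.28), Mmp9 (4.21), Klrb1c (0.0797), Cd8b1 (0.44) and Col1a2 (0.10). In GFPlow against WT it turned Bst2 (0.10), Hba-a1 (-0.0166) and Cd8b1 (0.71), of which Cd8b1 passed (adjusted p = 0.0459; -0.05 and not called with all libraries). Voom without that library gave Cd244a 1.21, Etfa 0.0177, Xbp1 -0.11, Irf4 -0.12, Cd74 -0.25, Bst2 0.21, Zbtb46 0.26, Mmp9 3.59, Cd8b1 0.44 and Col1a2 0.0209 in GFPhi against WT. It gave Lyz2 -1.79, Bst2 0.0709, Fcer1g -0.53, Cd8b1 0.69 and Hba-a1 -3.43 in GFPlow against WT, and Hba-a1 0.56 in GFPhi against GFPlow. Voom with weights gave 0.00726 for Bst2, 0.00978 for Zbtb46, 1.67 for Mmp9 and 0.0351 for Cd8b1 in GFPhi against WT. It gave -1.13 for Lyz2, -0.78 for Fcer1g, 0.28 for Cd8b1 and -3.13 for Hba-a1 in GFPlow against WT, and 0.47 for Hba-a1 in GFPhi against GFPlow. Without a filter Cd8b1 in GFPlow against WT was 0.00567. The cause was not tested.

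Over the fits with 1 library left out, values that turned in sign in GFPhi against WT ran from -2.64 to 1.37 for Cd244a, -0.79 to 0.00371 for Etfa, -0.36 to 0.32 for Cd22, -0.11 to 1.13 for Xbp1, -0.24 to 0.96 for Cd74, -0.29 to 0.22 for Bst2, -0.48 to 0.28 for Zbtb46, -2.60 to 4.03 for Mmp9, -1.38 to 0.0807 for Klrb1c, -0.55 to 1.60 for Fcer1g, -0.78 to 0.44 for Cd8b1, -3.02 to 0.25 for Hba-a1 and -3.30 to 0.10 for Col1a2. In GFPlow against WT they ran from -0.70 to 0.53 for Xbp1 (past the threshold against WT library 1 alone, adjusted p = 0.0062), -1.16 to 3.40 for Lyz2, -0.42 to 0.10 for Bst2, -1.97 to 1.51 for Fcer1g, -0.52 to 0.71 for Cd8b1 and -3.75 to 0.90 for Hba-a1. In GFPhi against GFPlow they ran from -0.0502 to 0.30 for Bst2, -1.48 to 3.07 for Fcer1g and -3.33 to 3.42 for Hba-a1. The cause was not tested.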

Other observations

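All tests in this part were chosen after the results were seen, apart from the splits of the 6 transgenic libraries, which were planned.

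Single libraries held genes that their group did not share, which were picked after their values were seen. Fos, an immediate early gene, was at 153.1 CPM in GFPhi library 1 and 195.2 CPM in GFPlow library 1, and at 4.224 to 10.77 CPM in the other 6. Jun was at 86.39 and 55.91 CPM in the same 2 libraries and at 1.448 to 7.27 CPM elsewhere. GFPlow library 2 held 58.68 CPM of Il21, a cytokine gene of follicular helper T cells, and 119 CPM of Igkc, an immunoglobulin light chain gene. Sostdc1 was at 45.8 CPM in GFPlow library 2 and 25.4 CPM in GFPlow library 1.

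In the 10 ways to split the 6 transgenic libraries 3 against 3, the real split gave 426 calls and the highest other 0, so the real split was 1 of 10. With 10 splits there are too few for a share under 0.05.

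WT library 1 differed from WT library 2 with an SD over genes of 1.145 in log2 CPM, against at most 0.350 for other pairs of 1 group. After a fit of transcript length and GC content the SD was 0.893, so the tables argue against these as the whole cause, though they took up 39.2% of the variance. Genes at 4 to 8 CPM elsewhere had no count in WT library 1 in 2.61% of cases, against at most 0.518% in any other library, which restates the lower number of genes detected and is no separate evidence of fewer molecules captured. Cell state and RNA quality were not tested as causes. No biological explanation was tested, as the labels give none that sets this library apart.

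Gt(ROSA)26Sor, a noncoding gene often used as a site for transgenes (ENSMUSG00000086429, GRCm38 chromosome 6, 113067428 to 113077333), was at 40.2 to 47.1 CPM in the 6 transgenic libraries, 77.7 CPM in WT library 2 and 286.5 CPM in WT library 1. It is annotated as antisense, and the strand of the counting is not known. As a hypothesis, 1 of 2 alleles may carry the transgene and yield no transcript: the median ratio to WT library 2 was 0.57 (0.517 to 0.607), but the band of ratios predicted was set after these were seen, so they are no independent test and the hypothesis stays open. Its neighbours Setd5 and Thumpd3 had median ratios of 1.32 and 0.867. WT library 1 was 3.69 times higher than WT library 2, which goes against an unusually high value in WT library 2, though a single library that stands apart does not settle it.

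Genes higher in both TIM-3+ sorts than in WT library 2 numbered 55 besides Havcr2 by DESeq2 without WT library 1. Cxcr6, Tbx21, Eomes, Il10, Fasl, Myo1f and Lair1 are among them. On the same 7 libraries edgeR called 0 genes in GFPhi against WT. Of all DESeq2 calls in GFPhi against WT there, only 5 (Havcr2, Ddx5, Sat1, Rgs10 and Cxcr6) were also made with WT library 1, directions not compared. Of these 5, only Cxcr6 is among the 55. GFPlow cells carried into the GFPhi sort would have to make up a median of 61.2% of its RNA to give the values of the 55 genes. The 55 were chosen as higher in GFPhi, which favours genes that need a large share. Among those named above, the need ran from 21.8% for Cxcr6 to 104% for Il10. Another 14 genes, abundant in GFPlow, bound that share at a median of 2.97% (-1.86% to 16.7%). The values thus argue against carried cells as the cause for most of the 55. They do not for those that need little, such as Nacc2 (4.19%), Slc16a5 (4.62%) and Iglv2 (9.19%), and Slc16a5 and Il21 are in both sets. In WT library 1 too, 78.2% of the 55 genes lay below every GFPhi library, against 67.3% at the upper limit of matched gene lists. Low values of WT library 2 alone and an effect of the TIM-3 transgene cannot be told apart with these 2 WT libraries. Nor can selection by the gates, TIM-3+ in both sorts and TIM-3- in WT, be told apart from the transgene.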
